A study of Homo sapiens with 24 samples.

How the data were processed

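RNA from 12 separate Caco-2 clones, each untreated and after 2 h with 100 ng/ml TNF, was sequenced in 24 libraries. Per the labels' protocols, libraries were stranded total RNA after rRNA removal, sequenced on either of 2 platforms, without saying which library ran on which. The deposited values are FPKM, 1 per merged locus, and per the file headers they come from Cufflinks. Per the submitters' processing notes, Trimmomatic 0.36, Bowtie2 2.3.4.3, TopHat2 2.1.1, Cufflinks 2.2.1 and Cuffdiff 2.2.1 were used with build hg19. The annotation is not given in the sources used here. The files hold 27133 loci with 25046 distinct symbols, of which 930 have several loci. Several of these loci can have the same coordinates: 4226 distinct coordinates are each shared by more than 1 locus. Of the loci, 5677 are at 0 in every library. EEF1A1, 1 of 16 abundant genes looked at, is listed at 0 in every library, so a 0 can be a failed estimate.

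Groups followed the labels: CFTRpos and CFTRneg, untreated and treated, 6 clones each. Replicates 1 to 3 and 4 to 6 of each group formed sequencing sets A and B, because their sample-sheet numbers repeat. The same clone gave both libraries of a replicate number within a genotype, as the clone names in the labels show. Libraries of 1 clone deviated together (r of 0.50 to 0.84, highest r with another clone 0.41, 12 of 12 highest with their own). Relative depth was estimated from steps in the values of 2883 sparse loci. The depth ratios of 66.1% of pairs of libraries lay within 5% of the estimate, where each library paired with itself was counted as outside. Depth in reads was not used here.

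Genes with at least 1 FPKM in at least 6 of the fitted libraries were tested. Values were rescaled by median-of-ratios factors, and log2(FPKM + 1) was fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0), with a trended prior variance and the sequencing set as a covariate. Tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, with 0.05 as the threshold. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The comparisons were genotype in untreated cells, genotype in treated cells, TNF in each genotype and the interaction of both. The main TNF and interaction fits did not pair the 2 libraries of a clone. Because these deviate together, the errors and p values of those fits are too large, and the fits with the clone as a block use the pairing. Because FPKM are not counts, no count test was used. CFTR and the mean TNF change of the NF-kB targets were tested with 1 value per clone by exact permutation over the 924 splits of 6 against 6 clones. Camera tested 17 gene lists at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 17 lists. They were NF-kB targets, chemokines and cytokines, immediate early genes, interferon-stimulated genes, MHC class I presentation, epithelial ion and bicarbonate transport, enterocyte differentiation, Wnt targets and intestinal stem cells, secretory cell markers, mesenchymal and EMT markers, epithelial junctions, cholesterol synthesis and uptake, the unfolded protein and integrated stress response, NRF2 and oxidative stress, hypoxia and glycolysis, cell cycle and p53 targets.

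Named genes were CFTR, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 FPKM in the higher group and the same direction in both sets (for TNF, in at least 5 of 6 clones), and up to 4 members of each list with the smallest p. XIST, Y-linked genes, small RNA genes and loci without a gene name, open reading frame names such as C6orf222 included, were left out of the rises and falls. Where fewer than 5 genes passed, the 5 with the smallest p were named, without genes placed on chromosome Y. Genes named outside this rule, among them those that passed only with the clone as a block, were chosen after their values were seen. The result of 1 gene is not reported here.

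Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, deposited values without rescaling, quantile normalization, a robust prior, no set term, each set alone, a replicate block, duplicateCorrelation by clone, and each clone left out in turn. Others were added after the values were seen: small RNA genes left out, clones S1 and E4 left out, chromosome medians subtracted, clone means, clones permuted within sets and only NF-kB targets of at least 20 FPKM. Chromosome medians used 8916 genes with a mean of at least 5 FPKM.

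The fits were tested on simulated data with 200 changed genes per comparison and noise drawn independently for each gene and library. So many changed genes ease the adjusted threshold, so the recovery does not hold where few genes change. Of genes changed by 1 log2 unit, 82% and 85% were recovered for genotype in untreated and treated cells, 82% and 92% for TNF in CFTRpos and CFTRneg clones, and 70% for the interaction. False calls were 5.76%, 1.60%, 5.29%, 4.5% and 5.75% of the calls in the same order. Tables and plots used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.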

Results

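The series measured RNA in Caco-2 cells, a line from a human colonic adenocarcinoma that forms a polarised epithelium in culture. CFTR encodes the chloride and bicarbonate channel that is defective in cystic fibrosis. All clones came from CRISPR/Cas9 mutagenesis of CFTR, in which a guided nuclease cuts the gene and its repair leaves mutations. The labels give the genotype NonCF for the 6 CFTRpos clones and CFTR null for the 6 CFTRneg clones. All 12 carry the same description of mutagenesis, and whether CFTRpos clones hold edits was not examined here. Each of the 12 clones gave an untreated library and a library made after 2 h with 100 ng/ml of TNF, an inflammatory cytokine, so 24 libraries fell into 4 groups of 6. The study set both genotypes side by side at rest and under this stimulus.

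Depth differed between libraries. No read counts were used, but steps in the low FPKM values gave relative depths from 0.583 to 1.44, with medians of 0.789 in replicates 1 to 3 of each group (sequencing set A) and 1.24 in replicates 4 to 6 (set B). Depth was lower after TNF in 6 of 6 CFTRpos clones (median 0.876 against 1.09), with more loci at 0 in all 6, and in 3 of 6 CFTRneg clones (1.10 against 1.18). Between 11880 and 12182 of the 27133 loci were above 1 FPKM in each library. Small RNA genes took 38.8% to 98.6% of the FPKM sum in set A and 16.1% to 40.1% in set B. MIR663A stood at 150344 to 31848800 FPKM in set A and at 1099 to 8072 FPKM in set B. The untreated CFTRpos replicate 1 held the highest share. Clone identity within set and genotype took 59.7% of the variance between libraries, sequencing set 14%, genotype 6.74%, TNF 4.15% and the interaction of genotype and TNF 1.23%. Clone has more degrees of freedom than each other term, so these shares do not rank the terms on equal footing.

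CFTR was measured first, as the targeted gene. Its transcript was lower in every CFTRneg library than in every CFTRpos library, but no CFTRneg library had lost it. Untreated CFTRpos clones held 87.2 ± 11.1 FPKM (SD, n = 6) and untreated CFTRneg clones 39 ± 21 FPKM (SD, n = 6). After TNF the values were 93.8 ± 12.4 and 39.7 ± 21 FPKM (SD, n = 6 each). CFTRneg libraries ran from 10.1 to 65.5 FPKM and CFTRpos libraries from 72.6 to 112 FPKM. The mean of log2(FPKM + 1) over both libraries of a clone was 1.39 lower in CFTRneg clones, a 2.63-fold difference (5.11 ± 0.98 against 6.50 ± 0.19, SD, n = 6 each; exact two-sided permutation test, p = 0.00216, the smallest that 924 splits allow). The difference was -1.47 in set A and -1.32 in set B, where 3 against 3 clones allow no p under 0.1. Across all tested genes the limma fit gave CFTR a log2 fold change of -1.36 (SE 0.36, adjusted p = 0.939) untreated. The gene lies at chromosome 7, 117120015 to 117308718, in hg19 (identifier XLOC_026621). TNF left CFTR without a called change in either genotype with limma. It was higher after TNF in 6 of 6 CFTRpos and 4 of 6 CFTRneg clones, by 0.09 and 0.03 log2 (with the clone as a block, SE 0.03 and 0.04, adjusted p = 0.394 and 0.795). RNA abundance says nothing of whether the remaining transcript encodes a working protein.

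**Figure D1:**
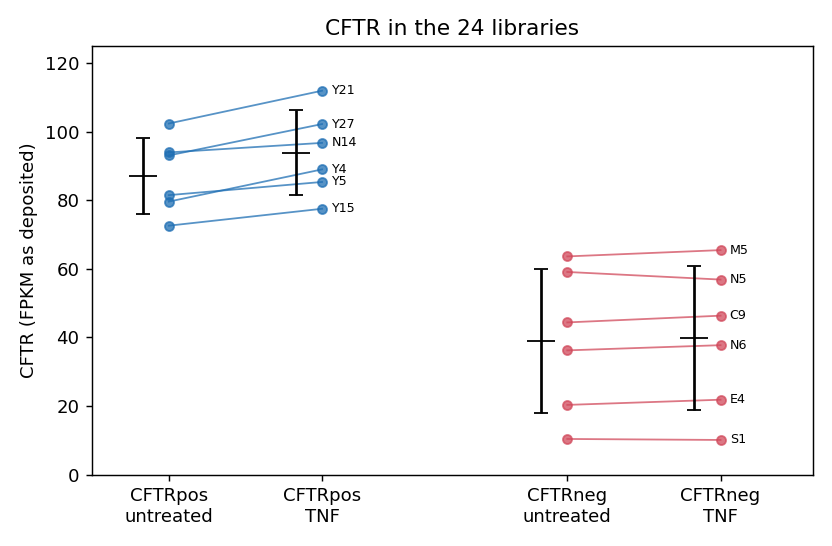
CFTR in FPKM as deposited (vertical axis) for the 24 libraries; lines join the untreated and the TNF library of 1 clone, whose name stands at the right, and black bars give the mean and SD of 6 clones. All 12 CFTRpos libraries lie at 72.6 FPKM or above and all 12 CFTRneg libraries at 65.5 FPKM or below, with clones S1 and E4 lowest.

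Clones also differed along whole chromosomes. CFTRneg clones S1 and E4 held the least CFTR, 11.9% and 23.9% of the CFTRpos median, and both had lower chromosome 7 genes than the other clones. In S1 the 274 genes of the long arm (above 60 Mb) had a median shift of -0.67 on the log2(FPKM + 1) scale, while the 153 genes of the short arm lay at 0.28. In E4 the short-arm and long-arm medians were -0.31 and -0.25. CFTR itself lay at -3.07 (S1) and -2.07 (E4), well beyond these long-arm medians. Its shift is taken from the CFTRpos median, and that of the arms from the other clones. The median over the genes of the other chromosomes was 0.01 in both clones. Of 276 pairs of clone and chromosome, 12 were shifted by at least 0.25 in both libraries of the clone, 7 in CFTRneg and 5 in CFTRpos clones. They included chromosome 5 in CFTRpos clone Y4 (-0.53), chromosome 19 in CFTRpos clone N14 (-0.39), chromosome 21 in E4 (-0.46) and chromosome 22 in CFTRneg clone C9 (0.44).

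**Figure D2:**
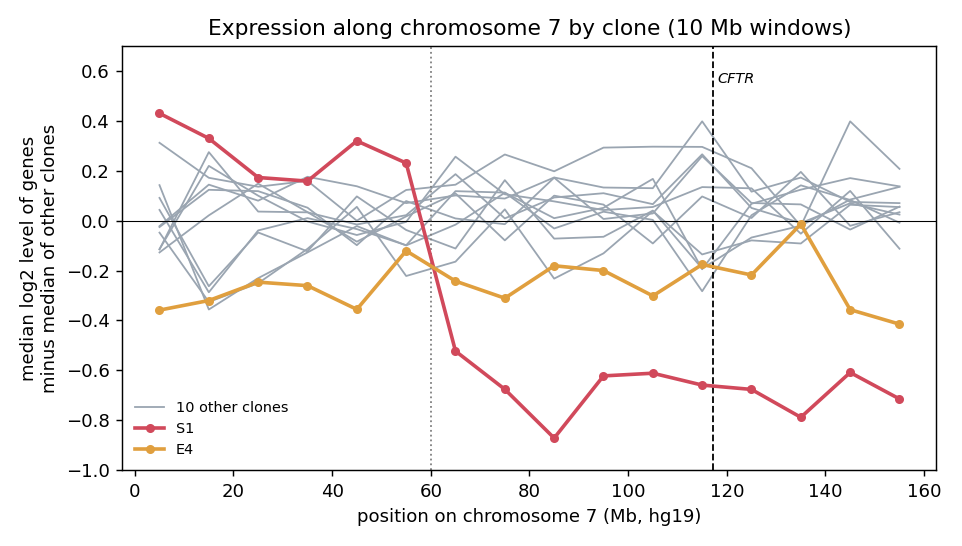
Median log2(FPKM + 1) of the genes in each 10 Mb window of chromosome 7 (horizontal axis, Mb in hg19) minus the median of the other clones, averaged over both libraries of a clone; dashed line, CFTR; dotted line, 60 Mb. Clone S1 lies between -0.87 and -0.52 in the 10 windows above 60 Mb and between 0.16 and 0.43 in the 6 below, and clone E4 lies below 0 in all 16 windows; the 10 other clones are grey.

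In CFTRpos clones, the largest called rises after 2 h of TNF were in TNFAIP3, CCL20, CXCL3, NFKBIA and CXCL8. TNFAIP3, which encodes the NF-kB inhibitor A20, went from 6.69 ± 2.3 to 59.9 ± 26.4 FPKM (SD, n = 6), a log2 change of 2.91 (SE 0.19, adjusted p = 9.73e-06). NFKBIA, which encodes the inhibitor IkB-alpha, went from 22.8 ± 2.34 to 152 ± 57.9 FPKM, a log2 change of 2.59 (SE 0.16, adjusted p = 6.30e-06). The chemokine genes CCL20, CXCL3 and CXCL8 rose by 2.87, 2.61 and 2.38 log2 (adjusted p = 0.0281, 0.0313 and 0.0305). The calcineurin inhibitor gene RCAN1 and the transcription factor genes ATF3, ELF3 and MAFF rose by 1.26, 1.17, 0.99 and 0.97 log2, and NCOA7 by 1.08. Each of these 10 genes was higher after TNF in 6 of 6 clones. CXCL8 was listed at 0 in 1 untreated CFTRpos library and at 0.0257 to 1.15 FPKM in the other 5, against 2.16 to 14.9 FPKM after TNF.

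In total 13 of 12066 tested genes rose, 9 of them at least 2-fold, and 0 fell with limma at an adjusted p under 0.05. The other 3 were C6orf222 (1.68 log2), NXPE3 and the ephrin receptor gene EPHA2. An unadjusted p under 0.05 was found for 201 genes, fewer than the 1 in 20 that chance gives, as this fit ignores the pairing. With the clone as a block, which removes the spread between clones, 117 genes rose and 21 fell, and all 13 were among them. That fit added CXCL2, CXCL10, IER3 and the transcription factor gene IRF1, which rose by 1.99, 2.26, 1.69 and 1.20 log2. Named after their values were seen, the BMP target gene ID1 and the pioneer factor gene FOXA1 fell in it by 0.40 and 0.25 log2 (adjusted p = 0.0419 and 0.0273). The count of 13 became 8, 3, 5 and 5 without replicates 1, 2, 3 and 6 in turn. In this fit without the block, CCL20, CXCL3 and CXCL8 did not pass without replicates 2, 3 or 6, nor with no filter. With the block, leaving out replicates 1 to 6 in turn gave 140, 68, 53, 72, 74 and 52 rises and 45, 11, 3, 7, 5 and 2 falls. The fall of ID1 passed in 0 of these 6 fits (adjusted p up to 0.169), that of FOXA1 in 2, without replicates 1 or 4 (up to 0.142), and the rises of CXCL2 and CXCL10 in 4 each, not without replicates 3 or 5 (up to 0.0631) and 3 or 6 (up to 0.0664). TNFAIP3 and NFKBIA passed in each of the sets alone, where 4 (set A) and 2 (set B) genes did.

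Among the lists fixed before the data were examined, 5 of 29 NF-kB targets rose (14 adjusted over the list alone; 15 with the block and 22 with the block over the list alone). Of 17 chemokines and cytokines 3 rose (5 over the list alone; 7 and 9 with the block), and of 30 immediate early genes 2 rose, ATF3 and MAFF (6 over the list alone, where FOS fell; 9 and 15 rose with the block, where 3 fell over the list alone). No p53 target passed (2 of 20 over the list alone), but PLK3, GADD45A and the proapoptotic gene BBC3 rose with the block by 1.08, 0.62 and 0.87 log2 (6 rose and 1 fell over the list alone). Camera placed these 4 lists above other genes (adjusted p of at most 3.04e-07), also with an estimated correlation (adjusted p of at most 0.00623). With the block and an estimated correlation none of the 17 lists passed (adjusted p of at least 0.0542). The other 13 lists had adjusted p of 0.0844 to 0.947, and with the block 1 member each passed among interferon-stimulated genes (IRF1), epithelial junctions (CLDN4, which rose), the unfolded protein response (XBP1, which rose) and Wnt targets and stem cell markers (RGMB, which fell). With a clone left out, IRF1, PLK3 and GADD45A passed in 6 of 6 fits and BBC3 in 5 (adjusted p = 0.0517 without replicate 6). CLDN4 passed in 3, not without replicates 2, 3 or 6, and XBP1 and RGMB only without replicate 1 (adjusted p up to 0.109, 0.127 and 0.149).

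In CFTRneg clones these 5 genes rose as well. The chemokine genes CXCL3, CXCL8, CCL20, CXCL10 and CXCL2 rose by 3.54, 3.54, 3.31, 3.07 and 3.06 log2 (adjusted p = 0.00787, 0.00786, 1.96e-05, 0.00107 and 0.00267). TNFAIP3 went from 7.01 ± 2.56 to 90.3 ± 34.2 FPKM (SD, n = 6), a log2 change of 3.48 (SE 0.27, adjusted p = 6.62e-05). NFKBIA went from 22.4 ± 2.44 to 197 ± 60.9 FPKM, a log2 change of 3.03 (SE 0.16, adjusted p = 3.45e-06). IER3, KLF10, IRF1 and the NF-kB cofactor gene BCL3 rose by 2.31, 1.58, 1.55 and 1.47 log2. All of these were higher in 6 of 6 clones. CXCL8 was listed at 0 in 1 untreated CFTRneg library and at 0.0176 to 0.209 FPKM in the other 5, against 2.96 to 38.8 FPKM after TNF.

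Here 41 of 12083 genes rose, 22 of them at least 2-fold, and 0 fell with limma. An unadjusted p under 0.05 was found for 329, again fewer than the 1 in 20 that chance gives. With the block 237 rose and 101 fell, again with all 41 among them. ID1 and FOXA1, named as above, fell with the block by 0.55 and 0.32 log2 (adjusted p = 0.0153 and 0.0363). The tight junction gene CLDN4, the intestinal stem cell factor gene SOX9 and the trefoil factor gene TFF1 rose with it by 0.45, 0.77 and 0.78 log2. The count of 41 became 21, 27, 22 and 19 without replicates 2, 4, 5 and 6 in turn. With the block, leaving out replicates 1 to 6 in turn gave 158, 175, 159, 208, 239 and 179 rises and 24, 31, 26, 41, 123 and 60 falls. ID1, CLDN4, SOX9 and TFF1 passed in all 6 of these fits, and FOXA1 in 2, not without replicates 1, 2, 3 or 6 (adjusted p up to 0.130). Set A alone called CCL20, and set B alone called DUSP5 and NFKBIA.

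By list, 12 of 31 NF-kB targets rose (23 adjusted over the list alone; 21 with the block and 27 with the block over the list alone). Of 19 chemokines and cytokines 6 rose (9; 11 and 12 by the same settings), of 30 immediate early genes 6 rose (15; 17 and 20, with 2 falls over the list alone under the block), and of 20 p53 targets BBC3 and PLK3 rose (4; 8 and 10). IRF1 was the 1 of 36 interferon-stimulated genes that passed (1; 3 and 3). With the block HMGCS1, INSIG1 and IDI1, 3 genes of cholesterol synthesis and its control, rose by 0.29, 0.46 and 0.24 log2, IDI1 not without replicate 3 (adjusted p = 0.0517). With the block 2 of 27 epithelial junction genes, 2 of 22 Wnt targets and stem cell markers, 2 of 30 unfolded protein response genes, 2 of 27 NRF2 targets, and 1 each of 32 enterocyte, 9 secretory and 31 hypoxia genes rose, while no member of the MHC class I, ion transport, mesenchymal or cell cycle lists passed. The hypoxia gene, SLC2A1, passed in 2 of 6 blocked limma fits with a clone left out, not without replicates 1, 2, 3 or 6 (adjusted p up to 0.106). Camera called 6 lists: the NF-kB, chemokine, immediate early and p53 lists (adjusted p of 4.91e-05, 1.57e-04, 0.00709 and 0.00701 with an estimated correlation), the epithelial junctions (adjusted p = 0.00701 with an estimated correlation) and the unfolded protein response (adjusted p = 0.0463, and adjusted p = 0.191 with an estimated correlation). With the block and an estimated correlation the first 3 passed (adjusted p = 0.0246), and the p53 list and the junctions had adjusted p = 0.0712 and 0.129. The other 11 lists had adjusted p of 0.0608 to 0.646.

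**Figure D3:**
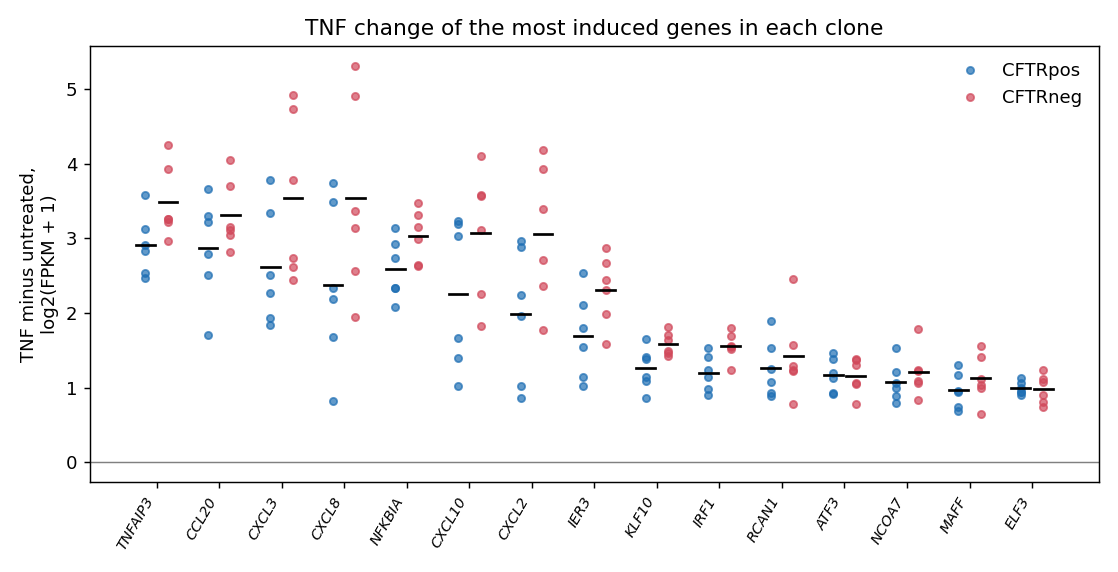
Change of log2(FPKM + 1) with TNF (vertical axis) for the 10 named genes with the largest called rises in each genotype, 15 genes in all; each point is 1 clone, 6 per genotype, and black lines are means. Every point lies above 0, and CXCL8 spans the widest range.

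The responses of the genotypes overlapped. Among 11884 genes tested in both, 10 were called higher in each (of 13 and 39), against 0.0427 for independent lists. With the block 101 rose in both (of 117 and 232 among 11883 genes, 2.28 for independent lists) and 10 fell in both (of 21 and 101, 0.178 for independent lists), among them ID1, FOXA1, ZNF398, ZNF526 and ZNF792. The falls rest on counts that ran from 2 to 45 and from 24 to 123 with 1 clone left out, each given above. Across genes, which are not independent replicates, the fold changes correlated with r = 0.54.

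The TNF response was then set between genotypes. Every one of the 10 CFTRpos genes above had its interaction term short of the threshold, and CXCL2 and NFKBIA had the largest terms relative to their error among NF-kB targets, at 1.07 (SE 0.56, adjusted p = 1) and 0.44 (SE 0.24, adjusted p = 1) log2, higher in CFTRneg. CXCL8 had 1.16 (SE 0.65, adjusted p = 1). With limma 0 of 12502 genes passed and 12 had an unadjusted p under 0.05. With the clone as a block 0 passed and 357 had an unadjusted p under 0.05. Both counts are under the 1 in 20 that chance gives. The fit without the block leaves the spread between clones in its error, so its p values are too large. The duplicateCorrelation fit, which keeps the clone as a random effect, called 1 gene, MIR141, which had an interaction term of -0.53 log2. The smallest p values in the fit without the block belonged to MIR141, MIR6087, SNORA62, SNORD9 and NR2F2-AS1, with adjusted p of 1.

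Of the 31 NF-kB targets, 29 had a larger estimated TNF change in CFTRneg clones, and of 20 chemokines and cytokines 17 did. These lists share members, among them CXCL2, CXCL3 and CXCL8, so their results are not separate. Camera called both lists (adjusted p = 0.00258 with an estimated correlation), but with the block and an estimated correlation their adjusted p was 0.279. The immediate early genes had an adjusted p of 1.25e-06 and, with an estimated correlation, an adjusted p of 0.212. The other 14 lists had adjusted p of 0.0841 to 0.960, and no list member passed. Per clone, the mean change of the 31 NF-kB targets was 0.98 ± 0.29 in CFTRpos and 1.31 ± 0.28 in CFTRneg clones (SD, n = 6 each). This difference of 0.33 on the log2(FPKM + 1) scale was within what regrouping of clones gave (exact two-sided permutation test, p = 0.0779; 0.515 adjusted over 17 lists). Within set A the difference was 0.20 (exact p = 0.6), and within set B it was 0.46 (exact p = 0.1, the smallest possible there). It reached an exact p of 0.0455, 0.0303 and 0.0390 without CFTRpos replicate 2, CFTRpos replicate 3 and CFTRneg replicate 4. Against CFTRpos clones, mean NF-kB target levels in CFTRneg clones were 0.11 lower untreated and 0.22 higher after TNF (exact permutation test, p = 0.212 and 0.175).

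**Figure D4:**
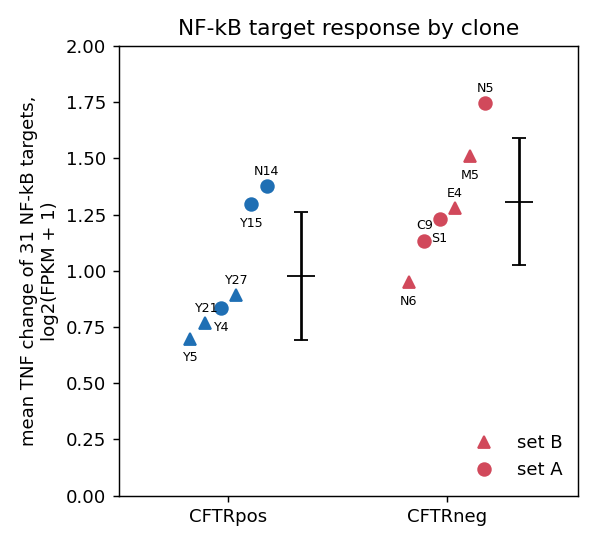
Mean change of log2(FPKM + 1) with TNF over 31 NF-kB targets (vertical axis) in each clone; circles are set A, triangles set B, and black bars give the mean and SD of 6 clones. CFTRpos clones lie between 0.70 and 1.38 and CFTRneg clones between 0.95 and 1.74.

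Between genotypes without TNF, no gene passed. Among genes not placed on chromosome Y, the smallest p values belonged to the Notch ligand gene DLL1, the GDNF family receptor gene GFRA3, the endosomal SNARE gene VAMP8, C12orf49 and LINC00669. DLL1 was at 4.1 ± 1.39 FPKM in CFTRneg and 1.64 ± 0.551 FPKM in CFTRpos clones (SD, n = 6 each), a log2 fold change of 0.93 (SE 0.18, adjusted p = 0.939). GFRA3 was at 9.96 ± 2.24 against 4.62 ± 1.66 FPKM, and VAMP8 at 49.6 ± 5.06 against 71.3 ± 7.58 FPKM. With limma 0 of 12061 genes passed, the smallest adjusted p was 0.939, and 523 genes had an unadjusted p under 0.05. In 13 genes the groups did not overlap, where chance gives 0.216%, or 26.1 genes. Set A alone called SNORD12B, and set B alone called 13 genes. In simulated data for this comparison, with 200 changed genes, the same fit recovered 82% of genes changed by 1 log2 unit and 98% of those changed by 2. So many changed genes ease the adjusted threshold, so this recovery does not hold where few genes change. In the real data CFTR itself did not pass.

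List members leaned in 1 direction without passing. Of 37 cell cycle genes 35 had higher estimates in CFTRneg clones, such as CCNB2 (0.47 log2) and CCNA2 (0.47 log2), and 30 of 34 enterocyte genes had lower ones, such as RBP2 (-0.90 log2) and the intestinal alkaline phosphatase gene ALPI (-0.83 log2). Of 27 epithelial junction genes 23 were estimated lower. Camera called these 3 lists (adjusted p of at most 0.0116), and none with an estimated correlation, where the adjusted p was 0.644 for the cell cycle and 0.299 for the enterocyte and junction lists. The other 14 lists had adjusted p of 0.0577 to 0.722. No list member passed over all genes, and over its list alone 1 immediate early gene, DUSP4, did (0.64 log2).

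After TNF the genotypes again had no gene past the threshold. GFRA3 and DLL1 stayed among the genes with the smallest p, at 1.09 (SE 0.19, adjusted p = 0.517) and 0.96 (SE 0.19, adjusted p = 0.754) log2, with the small RNA gene MIR6087, the protease gene FURIN (-0.57 log2) and the antiproliferative gene TOB1 (0.46 log2). CFTR had -1.42 (SE 0.36, adjusted p = 0.873). With limma 0 of 12039 genes passed, the smallest adjusted p was 0.457, and 633 had an unadjusted p under 0.05. The groups did not overlap in 21 genes, with 26.1 by chance (0.216%). Set A alone called ARIH1 and set B alone called 0 genes with limma. Camera called 6 lists, all lost with an estimated correlation. Cell cycle, cholesterol, Wnt and stem cell, immediate early and NF-kB lists were estimated higher in CFTRneg (adjusted p = 0.513, 0.516, 0.516, 0.372 and 0.513 with an estimated correlation), and the enterocyte list lower (adjusted p = 0.513 with an estimated correlation). The other 11 lists had adjusted p of 0.0941 to 0.995. In simulated data for this comparison, with 200 changed genes, 85% of genes changed by 1 log2 unit were recovered. That recovery does not hold where few genes change, and CFTR at -1.42 did not pass in the real data.

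The genotype fold changes of untreated and treated cells correlated across genes with r = 0.77 (covariance 0.0368). Because both rest on the same clones, 100 regroupings of the clones within sets were compared, the real one included. The other regroupings gave a median r of 0.76 (covariance 0.0341), and 39 of the 100 gave an r at least as large.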

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

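In this part, tests of library scaling, genes within 10 Mb of CFTR and the long arm were chosen after the result was seen. So were those of the NF-kB response and of the sequencing set. For the others the bounds were written before the run, but the lower chromosome 7 genes of S1 and E4 had been seen.

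Levels of 3 genes had 1 library far from the other 5 of its group. NFKBIA in untreated CFTRpos replicate 3 was at 4.83 on the log2(FPKM + 1) scale against 4.47 to 4.57 in the others (gap over range 0.724). CXCL8 in untreated CFTRpos replicate 4 was at 1.10 against 0 to 0.24 (0.782), and CCL20 in untreated CFTRneg replicate 6 at 3.16 against 1.96 to 2.33 (0.694). These were 3 of 74 groups tested, and chance gives about 1 in 20. In camera, the TNF responses of the genotypes were apart for NF-kB targets and for chemokines and cytokines (adjusted p = 0.00258 each with an estimated correlation), but not with the clone as a block and an estimated correlation (adjusted p = 0.279 each).

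The lower chromosome 7 genes of CFTRneg clones S1 and E4 came first among the patterns weighed. Chromosome 7 lay -0.48 (S1) and -0.29 (E4) from the other chromosomes, which library scaling or depth does not produce, as they act on all chromosomes. Because rescaling centres most genes, this comparison largely restates the shift that prompted it. By the bounds written beforehand, the short-arm median of 0.28 in S1 met what a change limited to the surroundings of CFTR predicts, and its 66.5% of chromosome 7 genes below 0 lay between both bounds for a loss of whole chromosome copies. Later tests changed that reading: long-arm genes over 10 Mb before CFTR were at -0.65 in S1, which a local change forbids, and 96.0% of long-arm genes were below 0, consistent with fewer copies of the long arm, while the raised short arm argues against loss of the whole chromosome. In E4 the short-arm median of -0.31, the -0.26 over 10 Mb before CFTR and the 83.4% of genes below 0 argue against a local change and are consistent with fewer copies of the chromosome; DNA was not analysed here, so copy number stays a hypothesis.

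The larger NF-kB response of CFTRneg clones was weighed next. Without rescaling the difference was 0.31 (exact p = 0.0844), and over the 9 of 31 members of at least 20 FPKM it was 0.31 (exact p = 0.0758). Both values lay near the real 0.33 and above the 0.1 under which library scaling or a floor of low values would have brought them, but the real difference itself had an exact p of 0.0779, so the spread between clones leaves both explanations open. Of the 924 splits of the clones 72 differed as much as the real 0.33, with 0.53 the highest of the others, so the grouping of clones by chance stays open, as does an effect of genotype.

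The spread between clones of 1 genotype was weighed last. Subtracting 1 median per chromosome removed 12.9% of the spread within genotype and set, so shifts of whole chromosomes are not its main source. A single median cannot remove shifts of an arm or segment, so those were not tested. Of the variance between all libraries, a different total, the sequencing set took 14% and clones within genotype and set 59.7%. The clone term has more degrees of freedom, and each set holds different clones, so these shares do not settle whether the set is the main source. No biological explanation was tested.

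Other splits of the same libraries were counted, the real one included. The genotype and interaction fits called 0 genes with limma, a count that every split reaches (100 of 100 each), so the splits decide nothing there. The highest other counts were 4 for genotype in untreated cells, 3 in treated cells and 1 for the interaction. For lists, 82 and 36 of 100 splits called as many as the real 3 and 6 for genotype in untreated and treated cells (highest other 9 and 10), and 46 of 100 as many as the real 3 for the interaction (highest other 6), so chance was not excluded. The correlation of genotype effects, 0.77, was reached by 39 of 100 regroupings (highest other 0.88). For TNF, 1 of 100 splits, the real one, reached 13 genes in CFTRpos (highest other 1) and 1 of 100 reached 41 in CFTRneg (highest other 0). Among 32 splits that part every clone's pair, 1 reached 13 (highest other 1) and 1 reached 41 (highest other 0), and with the clone as a block 1 of 32 reached 138 (highest other 0) and 1 of 32 reached 338 (highest other 1).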

How the results depend on the processing

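Small RNA genes left out, clones S1 and E4 left out, chromosome medians subtracted, clone means, permutation within sets and NF-kB targets of at least 20 FPKM were chosen after the values were seen. With limma, the genotype counts of 0 stayed 0 in all settings but single sets: untreated, set A called 1 gene and set B 13, and treated, set A called 1. The 13 genes of TNF in CFTRpos became 5 with no filter, 4 in set A, 2 in set B, 138 with the replicate block, 233 with duplicateCorrelation and 3 to 14 in leave-one-out (8, 3, 5 and 5 without CFTRpos replicate 1, 2, 3 and 6). The 41 of CFTRneg became 1 in set A, 2 in set B, 338 with the replicate block, 516 with duplicateCorrelation and 19 to 30 in leave-one-out (21, 27, 22 and 19 without CFTRneg replicate 2, 4, 5 and 6). The block removes the spread between clones by construction, and duplicateCorrelation models the correlation between the libraries of a clone. Single sets and leave-one-out have fewer samples. The blocked counts ran from 54 to 185 (2 to 45 falls) and from 182 to 362 (24 to 123 falls) with a clone left out. The interaction count of 0 became 1 with duplicateCorrelation. List calls went from 3 and 6 to 0 and 0 for genotype with an estimated correlation. They went from 4 to 7 for TNF in CFTRpos with the replicate block, and to 0 with the block and an estimated correlation. The correlation of genotype effects fell from 0.77 to 0.56 with a mean of at least 5 FPKM, and the cause was not tested. The CFTR difference was -1.47 in set A and -1.32 in set B (exact p = 0.1 each, the smallest possible) and -1.58 to -1.06 in leave-one-out. The NF-kB response difference was 0.24 to 0.41 in leave-one-out, with an exact p under 0.05 at 0.39, 0.41 and 0.40 without CFTRpos replicate 2, CFTRpos replicate 3 and CFTRneg replicate 4. Replicate numbers link different clones between genotypes (r of -0.02 to 0.30; 3 of 6 best with their own number in each treatment), and that block left both counts at 0. Without small RNA genes the TNF counts were 14 and 42. With the block the list calls also went from 6 to 7 for TNF in CFTRneg, from 3 to 4 for the interaction and from 6 to 5 for genotype in treated cells. With the block and an estimated correlation, 3, 0 and 0 lists were left in the same order. Of the values of named genes under alternatives, 4254 were the same, 65 stronger, 59 weaker and 0 reversed. A value was the same if it stayed on its side of the threshold, whatever its direction where neither fit passed. Only values that passed in the main fit could be reversed, so those of genotype and interaction could not. Leave-one-out fits were left out of this tally. The planned count test was not run because the values are FPKM. Set A, with the lower relative depth, had a median of 9669 loci at 0 against 9296 in set B, and 11965 against 11957 above 1 FPKM.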

Other observations

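In this part, the class of zinc finger genes, the tests on it and the genes named were chosen after the falls under TNF were seen. For the comparison with level-matched lists only the bounds were written before it was run.

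Some single genes outside the inflammatory lists passed under TNF in the limma fit with the clone as a block, while the junction and secretory lists had adjusted p = 0.621 and 0.53 in CFTRpos and 0.129 and 0.557 in CFTRneg clones in camera with that block and an estimated correlation. The tight junction gene CLDN4 rose by 0.40 log2 in CFTRpos and 0.45 in CFTRneg clones (SE 0.06 and 0.06, n = 6 each). XBP1, a transcription factor gene of the unfolded protein response, rose by 0.25 and 0.24. In CFTRneg clones the membrane mucin gene MUC13 rose by 0.35 and the cyclin gene CCND1 by 0.34, and their CFTRpos values were 0.20 and 0.29 without passing. The 4 CFTRneg rises passed with any 1 clone left out. In CFTRpos clones CLDN4 did not pass without replicates 2, 3 or 6, and XBP1 passed only without replicate 1 (adjusted p up to 0.109 and 0.127). SOCS1, a cytokine signalling inhibitor gene, fell by 0.39 in CFTRpos clones and had a value of -0.39 in CFTRneg clones without passing. Its CFTRpos fall did not pass without replicates 2, 3, 4 or 6 (adjusted p up to 0.0986).

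Many genes that fell with the block were zinc finger genes named ZNF. They made up 8 of 21 falls in CFTRpos clones (38.1%, against 2.88% of tested genes; Fisher exact p = 6.34e-08) and 21 of 101 in CFTRneg clones (20.8%, against 2.91%; Fisher exact p = 9.12e-13), with 0 and 3 ZNF genes among the rises. Leaving out replicates 1 to 6 in turn gave 14 of 45, 3 of 11, 2 of 3, 2 of 7, 2 of 5 and 1 of 2 falls in CFTRpos and 5 of 24, 4 of 31, 5 of 26, 8 of 41, 22 of 123 and 10 of 60 in CFTRneg clones. The median change of tested ZNF genes was -0.11 and -0.09, and of 10000 random lists matched on level 0 were as low in either genotype, so their low level does not account for it. The lists drew genes as if these changed independently, and the class was picked from these same falls. In 11 of 12 clones the ZNF median was below that of other genes, with E4 the exception at 0.02. The hypothesis that ZNF transcripts as a class decrease within 2 h of TNF is consistent with these values, and it was found and tested on the same data.

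Further chromosome-wide shifts were chromosome 10 in S1 (-0.32), chromosome 11 in CFTRneg clone N5 (0.29), chromosome 14 and 22 in CFTRpos clone Y15 (-0.31 and 0.36), chromosome 16 in C9 (0.35) and chromosome 22 in CFTRpos clone Y5 (0.29).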
